A study of Helianthus annuus with 6 samples.

How the data were processed

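RNA from leaf discs of sunflower (Helianthus annuus) was hybridised to 6 single-colour (Cy3) Agilent oligonucleotide arrays. Per the labels' protocols, plants at the V3 stage were grown under 16 h of light and 8 h of darkness at 25 °C, Trizol extraction of 100 mg of frozen discs gave total RNA, which was treated with DNase I, and labelled cRNA was made from 0.5 µg of RNA. The arrays fell into 2 groups of 3, taken from the sample titles: discs carrying a 35S promoter in front of the GUS reporter (control) and discs carrying a 35S promoter in front of HaWRKY10. The series' design text calls the replicates biological and names HaHB11, not HaWRKY10, as the expressed factor. The titles of the 3 control samples name pBI121, whereas the titles and construct labels of the 3 other samples name HaWRKY10. The sample labels were followed. Nothing in the sources used here settles the disagreement.

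The intensity values are those of the authors' scanner files, 1 file per array. Per the file headers they were made with Agilent Feature Extraction 11.5.1.1, whereas the submitters' processing notes name version 9.1. Per the file headers, the deposited processed signal is a background-subtracted and spatially detrended intensity in which very low spots carry a small positive surrogate value, and no scaling between arrays had been applied. The same files hold the median spot intensity, the median local background and flags for each spot, but no mean spot signal column. The deposited series table holds 1 log2 value per probe and array. Per column its values correlated with the log2 processed signal of the same array at 0.9996 or more over the tested probes, ran in the same direction with a slope of 0.948 to 1, and had a median of 4.26 on each of the 6 arrays over all probes. They differed from a quantile normalisation of the processed signal by a median of 0.064 to 0.0722 log2 units, so how exactly the authors made them is not given in the sources used here. That log2 table served only as an alternative.

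Each array held 42326 spots, of which 40909 were not control spots and belonged to 40243 probes. Of these probes 74 were spotted 10 times and the others once. Spots with an outlier flag were left out, and 11 probes with no unflagged spot on some array were not tested. The log2 processed signal was averaged over the spots of a probe, and each array's 75th percentile was subtracted. A probe was tested when it was well above background, by the scanner software's flag, on at least 3 of the 6 arrays, counted without regard to group, which left 21326 probes (53% of those on the array). The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 6 arrays, no covariate), and p-values were adjusted by the Benjamini-Hochberg method over the tested probes, with a threshold of 0.05. No p-value was taken from the deposited files. Levels are given below as log2 units relative to the 75th percentile of the array, with the SD over 3 arrays. The number of arrays limits the precision: the median standard error of a difference was 0.153 log2 units, and the median 95% confidence half-width was 0.365, a ratio of 1.29.

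Both arrays with the same replicate number lay on the same slide and were scanned together, per the file headers, so each of the 3 slides held 1 array of each group. Deviations from the group means correlated across probes at 0.173, 0.249 and 0.232 between arrays of the same number, all above 0.1, and at -0.225 to 0.024 between arrays of different numbers. Deviations within a group cancel out for each probe, so positive values at the same number make the others negative on average. The contrast between these ranges is therefore partly built in. Given the shared slides as well, the numbers were taken to pair the arrays. The fit with slide as a replicate block is given beside each result that it changes.

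The comparison was tested on simulated data drawn from the real probe means and spreads of this comparison, with 200 of the 21326 probes changed in each of 10 runs. The fit called 53.4% of probes changed 2-fold, 88.6% of those changed 4-fold, 97.2% of those changed 8-fold and 98.8% of those changed 16-fold, all with the right sign. Over the 10 runs it called 1690 changed and 94 unchanged probes. With no probe changed it made 0 calls over 10 runs. Each run mixed all these sizes, 50 probes of each, and many true calls loosen the adjusted threshold for the rest. The simulated noise was normal and independent between probes, with no slide effect. These rates are therefore not the power for a 2-fold change in the real data, where 1 probe passed.

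The array's probes carry only identifiers of the custom design, or an EST accession for the 74 replicated ones, and neither the files nor the gene table of the sunflower assembly HanXRQr2.0 used here pairs them with genes. The probes of HaWRKY10 and HaHB11 and 28 gene lists fixed before the data were examined were therefore not analysed here. The rule for the probes named in the text was also fixed before the data were examined: those past the threshold with no overlap between the groups, by size of change, then the non-overlapping probes of smallest p, and at most 2 in each direction when no gene name could be had. Alternatives fixed before the data were examined were normexp background correction with an offset of 50 (on the median spot signal, in place of a mean), quantile and median scaling, no filter and a stricter filter on dim probes, slide as a fixed and as a random block, a variance trend with robust eBayes, other thresholds, the deposited log2 table, and leaving out each array in turn. The remaining alternatives were chosen after seeing the data and are named as such below.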

Results

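Transcript levels were measured in discs cut from young sunflower leaves that transiently carried 1 of 2 constructs. In 3 samples the constitutive 35S promoter drove the GUS reporter, an enzyme used as a control insert. In 3 samples it drove HaWRKY10, a sunflower transcription factor of the WRKY family. The comparison asks which transcripts of the leaf differ when the factor is expressed, in a study whose title concerns the mobilisation of seed-stored reserves. No probe of the array is paired with a gene in the sources used here, so transcripts are given by probe, and the level of the expressed factor itself was not analysed.

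The arrays measured similar parts of the leaf transcriptome. Between 21021 and 21285 of the 40243 probes were well above background on the control arrays, against 21289 to 21760 on the HaWRKY10 arrays. The 75th percentile of the processed signal was 302, 205 and 201 intensity units on control arrays 1 to 3, and 255, 236 and 265 on HaWRKY10 arrays 1 to 3. The median local background lay between 24 and 28.5 units on all arrays, and no probe spot was saturated. Among the probes spotted 10 times, the median SD over the spots of one array was 0.0666 to 0.0765 log2 units. Over the 50 of these probes that were tested, the median SD between arrays of one group was 0.216, so spot noise was the smaller part of their error. Probes spotted once give no such measure.

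The leaf transcriptome of the 2 groups differed little in size. The median absolute difference over the 21326 tested probes was 0.161 log2 units, and 98.3% of probes lay within a 2-fold difference of means. A mean at least 2-fold higher with HaWRKY10 was measured for 150 probes, and at least 2-fold lower for 212 probes. With the arrays scaled to their median instead of their 75th percentile these numbers were 201 and 170, and without control replicate 3 they were 261 and 247, so the side with more of them depended on the scaling and on that array. After normexp background correction they were 39 and 83. Of the probes with a 2-fold difference, 79 higher and 171 lower ones had no overlap between the 3 arrays of each group. Among all tested probes without overlap, whatever the size of the difference, 2129 were higher and 1983 lower.

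One transcript fell with HaWRKY10 past the limma threshold, and none rose past it, although 1214 probes were higher at an unadjusted p under 0.05. The signal of probe CUST_1096_PI423492394 was 1.98 ± 0.11 in the control (SD, n = 3) and 0.42 ± 0.03 with HaWRKY10 (SD, n = 3), a 2.94-fold lower mean. The log2 difference was -1.55 with a standard error of 0.11 (95% confidence interval -1.81 to -1.30, limma adjusted p = 0.0498). It was -1.68, -1.56 and -1.42 within slides 1, 2 and 3. That shared direction follows from the lack of overlap required of a named probe. With slide as a replicate block the limma adjusted p was 0.153 and the count of calls was 0 (3212 probes at an unadjusted p under 0.05). Leaving out any 1 array other than control replicate 3 also ended this call, with adjusted p-values of 0.205 to 0.472. Without control replicate 3 the fit called 10 probes. With a variance trend and robust eBayes 3 probes were called higher and 3 lower, with these and the slide block 41 higher and 37 lower, and after normexp background correction 17 higher and 41 lower, so the count of calls and the absence of rising ones depended on the setting.

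The 3 further probes named by the rule had non-overlapping groups but did not pass with the same settings. Probe CUST_7245_PI423492394 measured 1.12 ± 0.16 in the control and 2.49 ± 0.10 with HaWRKY10 (SD, n = 3 each), a ratio of 2.60 with a limma adjusted p of 0.129. Probe CUST_6910_PI423492394, one of the brightest on the array with a mean signal at percentile 98.7 of the tested probes, measured 5.92 ± 0.11 in the control and 7.07 ± 0.12 with HaWRKY10, a ratio of 2.22 (limma adjusted p = 0.129). Both rising probes passed after normexp (limma adjusted p = 0.0216 for each) and with a variance trend and robust eBayes (0.0213 and 0.0448). With the trend, robust eBayes and slide block together they also passed (0.00453 and 0.0197). Neither passed with the slide block alone (limma adjusted p = 0.153 and 0.179) or in the deposited log2 table (0.151 and 0.185). Over 24 alternatives they passed in 9 and 8. Probe CUST_19499_PI423492394 measured -2.08 ± 0.09 in the control and -3.77 ± 0.28 with HaWRKY10, a ratio of 3.22 toward the control (limma adjusted p = 0.129). This probe is dim, and its log2 difference of -1.69 was -0.51 after normexp background correction; it passed only with the trend, robust eBayes and slide block together (adjusted p = 0.0266). All 4 named probes were well above background on all 6 arrays.

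**Figure D1:**
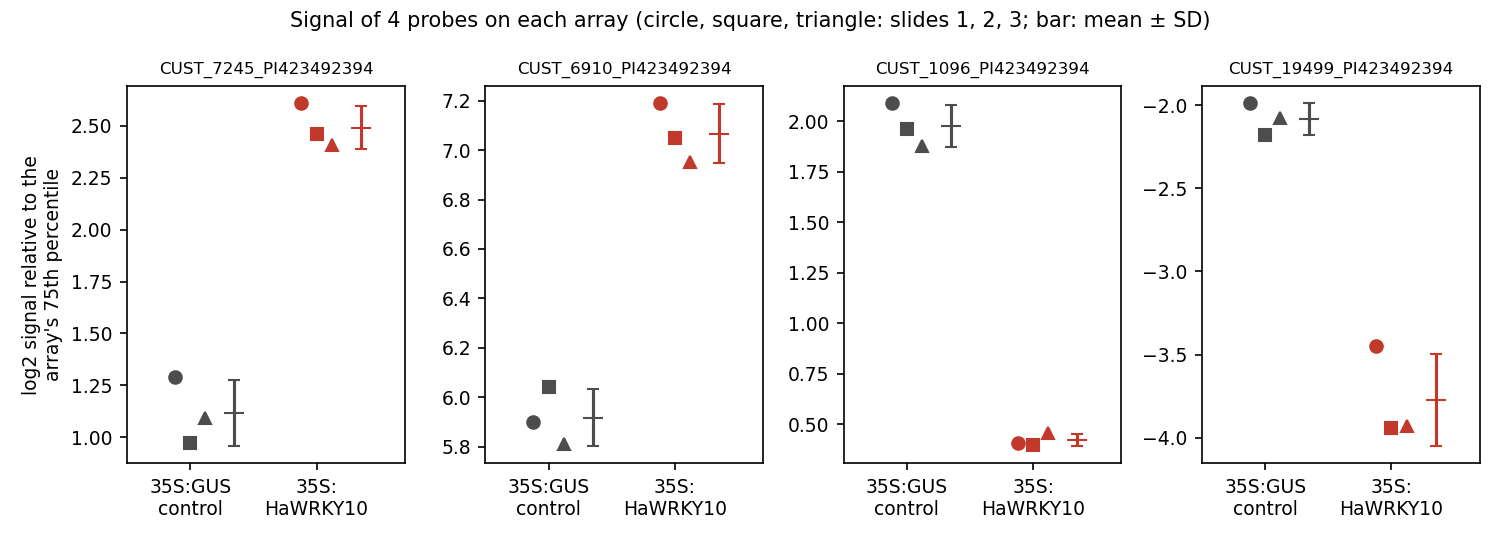
Signal of the 4 named probes on each array, in log2 units relative to the array's 75th percentile, with a separate vertical axis for each probe; the bars give the mean ± SD of 3 arrays. The groups do not overlap for any of the 4, and CUST_1096_PI423492394 is the one with an adjusted p under 0.05.

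The largest mean differences were several times greater than these but varied more between arrays. The probe with the largest rise was measured at -0.06, -1.22 and 1.53 on control arrays 1 to 3 and at 3.61, 3.83 and 3.67 on HaWRKY10 arrays 1 to 3, a 12.3-fold difference of means (limma adjusted p = 0.193). The largest fall measured on both sides was that of a probe at 1.03, 0.56 and -0.65 on control arrays 1 to 3 and at -3.53, -2.31 and -4.03 on HaWRKY10 arrays 1 to 3, a 12.1-fold difference of means (limma adjusted p = 0.193). Both probes were well above background on all 6 arrays, and neither passed the threshold.

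**Figure D2:**
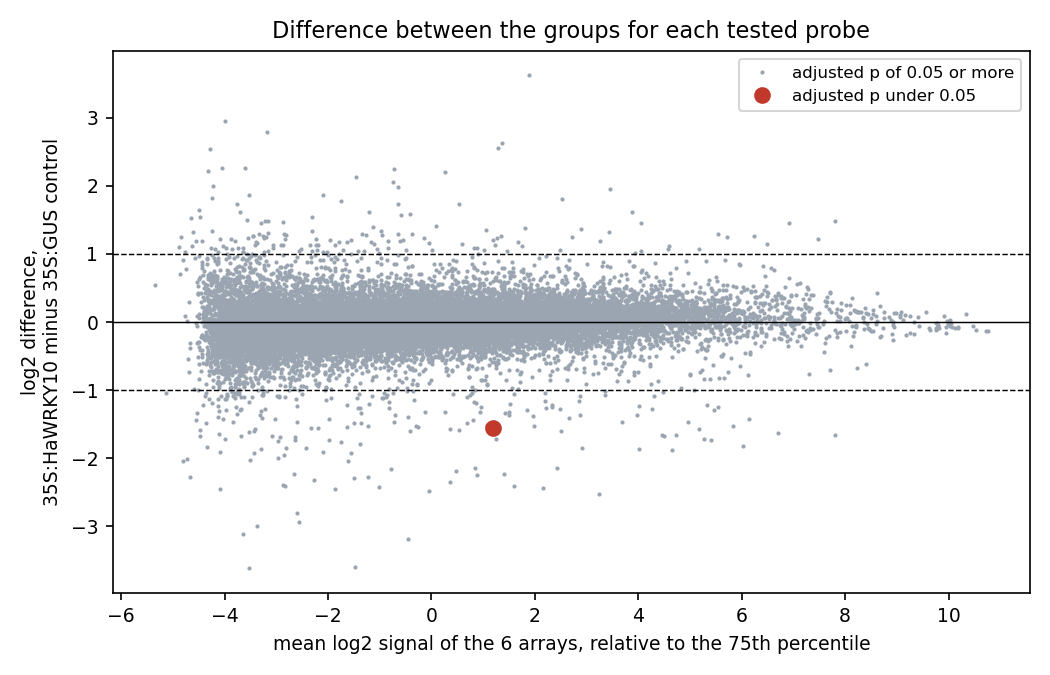
Log2 difference between the group means (HaWRKY10 minus control) against the mean log2 signal for each of the 21326 tested probes, with dashed lines at 2-fold. Most 2-fold differences lie among dim probes (246 at mean signals below the median of the tested probes, 116 above it), and the 1 probe past the threshold is drawn in red.

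Some transcripts were measured above background in one group alone. A set of 48 probes was well above background on all 3 HaWRKY10 arrays and on no control array, and 19 probes showed the opposite. Because the dim group gives only a bound, the difference is a lower limit, taken between the mean of the bright group and, on each dim array, the higher of the probe's own signal and the lowest signal among probes well above background. The limits were at least 3.20-fold at most and 1.27-fold in the median for the probes measured with HaWRKY10, except that 1 probe had a limit under 1. For the probes measured in the control they were at least 6.60-fold at most and 1.87-fold in the median. Their lowest limma adjusted p was 0.193 in the first set and 0.137 in the second, so none passed. The 9 other groupings of the 6 arrays into 3 and 3 gave 31 to 61 such probes, against 67 in all here.

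More probes differed at an unadjusted level than the number of tests would give, except in 1 setting. An unadjusted limma p under 0.05 was found for 2612 probes (12.2%), 1214 higher and 1398 lower, where 1066 would be expected if no probe differed. The count was 2465 under quantile normalisation, 2827 under median scaling, 3212 with the slide block, 3590 without control replicate 3, 1546 without HaWRKY10 replicate 1 and 1533 after normexp background correction. With normexp and median scaling together, a setting chosen after the data were seen, it was 645, below the expected number. The groups did not overlap for 4112 probes (19.3%, against 10% by chance for 3 arrays against 3), and the HaWRKY10 array exceeded, or fell below, the control on all 3 slides for 40.8% of probes, against 25% by chance. Across probes, which are not independent replicates, the log2 ratios of slides 1 and 2 correlated at 0.425, those of slides 1 and 3 at 0.324 and those of slides 2 and 3 at 0.159. Within single slides, each with 1 array per group, 395, 343 and 390 probes were at least 2-fold higher with HaWRKY10 on slides 1, 2 and 3, and 432, 347 and 538 were at least 2-fold lower.

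The 74 probes spotted 10 times, which represent ESTs, showed no large difference. Of the 50 that were tested, 28 had a higher mean and 22 a lower mean with HaWRKY10, the largest absolute difference was 0.84 log2 units, and 3 had an unadjusted limma p under 0.05. None passed the adjusted threshold.

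The arrays of the HaWRKY10 group resembled each other more than the control arrays did. Across the tested probes, pairs of HaWRKY10 arrays correlated at 0.9871 to 0.9908. Control arrays 1 and 2 correlated at 0.9892, whereas control array 3 correlated with them at 0.9826 and 0.9791 and with the HaWRKY10 arrays at 0.9825 to 0.9832. The median SD per probe was 0.188 log2 units in the control and 0.156 with HaWRKY10.

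**Figure D3:**
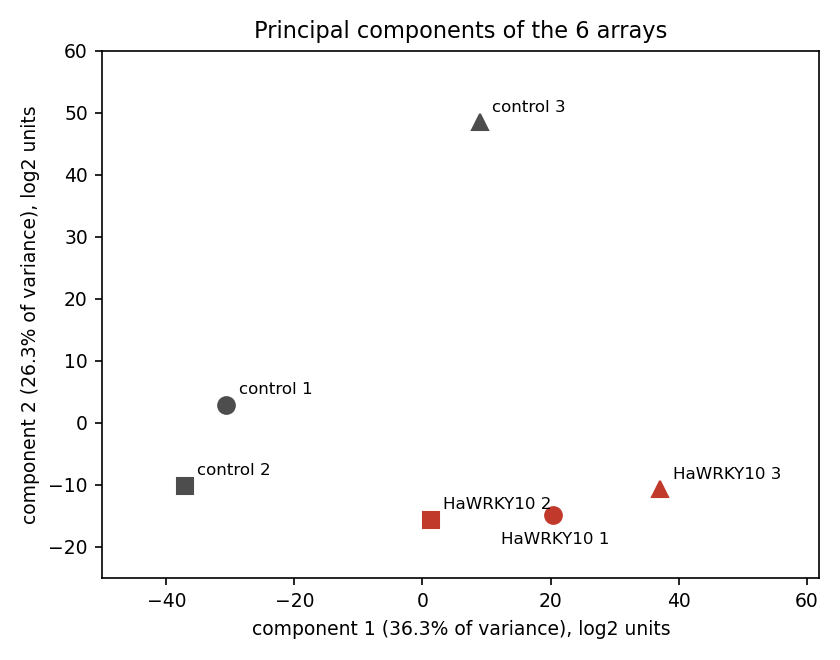
First and second principal components of the 6 arrays over the tested probes, in log2 units; grey marks the control and red HaWRKY10, and the marker shape gives the slide. The first component (36.3% of the variance) has control arrays 1 and 2 at one end and HaWRKY10 array 3 at the other, and control array 3 lies apart from all others on the second (26.3%).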

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

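The settings that combine normexp with another choice, drop its offset, add a constant to the processed signal or keep only probes brighter than the median were chosen after seeing the data. The count of 1 probe past the limma adjusted threshold, which was also at least 2-fold, stayed at 1 when probes had to be well above background on all 6 arrays, with slide as a random replicate block, and in the authors' log2 table. At an unadjusted p under 0.05, quantile normalisation gave 2465 probes, median scaling 2827, the fixed replicate block 3212 and normexp with median scaling 645. By chance 1066 of their 21326 tested probes would be expected. No filter on dim probes gave 3289 of 40232, to which 1066 does not apply. The count of calls fell to 0 in all these settings, after normexp without an offset and at an adjusted p under 0.01. It rose to 6 with a variance trend and robust eBayes (6 at least 2-fold), 78 with these and the replicate block (41 higher, 37 lower; 51 at least 2-fold), 58 after normexp (43), 259 after normexp with the replicate block (109), 4 after normexp with quantile normalisation (3), 144 after normexp without control replicate 3 (102), 8 with 50 added to the processed signal (8), 34 with 100 added (24) and 7 among probes brighter than the median (7). Leaving out 1 array in turn gave 0 to 10 probes, 0 to 10 of them at least 2-fold: 10 without control replicate 3 (7 higher, 3 lower) and 0 without any other. Apart from the normexp counts, weighed under the other observations, the cause was not tested. The differences of the 4 named probes kept their direction in all 95 cases run, most of which could not have reversed it. The probes were named for non-overlapping groups in these data, so leaving out an array cannot turn the sign. Settings that change only the filter, the block or the variance model reuse the same difference. CUST_1096_PI423492394 ranged from -1.60 to -1.29 and passed in 13 of 24 alternatives, with adjusted p-values of 0.000986 to 0.503. CUST_7245_PI423492394 passed in 9 of 24, CUST_6910_PI423492394 in 8 of 24 and CUST_19499_PI423492394, which ranged from -1.85 to -0.47, in 1 of 23. Of the 2-fold differences of means, the share that was higher with HaWRKY10 was 41.4%, 54.2% under median scaling, 32% after normexp and 30.4% without the filter. Low signal over background limits the dim probes: the median SD within groups was 0.243 log2 units for probes dimmer than the median and 0.15 for brighter ones. With 10 splits of the 6 arrays into 3 and 3, no share under 0.05 can be reached: the real split gave 1 probe past the threshold (1 at least 2-fold), the highest other split gave 1, and 4 of the 10 splits gave as many; the 3 other splits that part every slide pair, as the labels do, gave 0.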

Other observations

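The tests of exchanged labels and of a single wrong label were chosen after the results were seen. So were those of the constant added before the log and of other splits. For the other tests below, the prediction was written before the test was run, but after the pattern it concerns had been seen. Adding 100 to the processed signal and combining normexp with median scaling or quantile normalisation were also chosen after seeing the data.

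Control replicate 3 lay between the groups. Among 450 probes whose means differed at least 2-fold without overlap between control arrays 1 and 2 and the HaWRKY10 arrays, its median position was 0.571 of the way to HaWRKY10 (bootstrap 95% interval over probes 0.48 to 0.645), whereas the same measure for the other 5 arrays, each left out in turn, was between -0.013 and 0.419. Dim-probe noise stays open. The position was 0.508 (0.281 to 0.706) among the probes brighter than the median, above the bound of 0.25 set before the test. That bound ignored that left-out arrays can fall short of their group on probes chosen for separation. The interval also spans the 0.419 of HaWRKY10 replicate 2. An additive effect of its slide stays open too. On probes chosen without either array, control replicate 3 lay at 0.534 and HaWRKY10 replicate 3, on that slide, 0.073 past its own group. When left out, HaWRKY10 replicates 1 and 2 fell short of their group by 0.241 and 0.419. A place 0.073 past it can therefore hold a slide shift. With control replicate 3 scaled like the others, a fixed share of HaWRKY10 RNA in it would give rising and falling probes the same linear position. The positions were 0.721 and 0.314, which argues against such a share alone. A share together with a scaling offset of that array was not tested. An exchange of labels with HaWRKY10 replicate 2 would place both arrays past 0.5 of the way to the other group. On 635 probes chosen without both arrays, HaWRKY10 replicate 2 lay at 0.405 (0.371 to 0.432), which argues against the exchange. Control replicate 3 lay at 0.557 (0.499 to 0.63) on these probes, a place that an exchange would also give. A single wrong label cannot be told apart from a control sample that differed, because HaWRKY10 replicate 2 itself lay 0.419 of the way toward the control and the interval around 0.571 spans the mirror of that value; a difference between discs or plants remains a candidate explanation and was not tested.

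More probes passed after normexp with an offset of 50 than from the processed signal: 58, of which 17 were higher and 41 lower with HaWRKY10, and 48 were brighter than the median. The setting changed the signal column, the background correction and the constant together. The constant added before the log is a candidate contributor, since normexp without it gave 0 calls, but it did not give the calls by itself: with the constant kept, median scaling gave 0 and quantile normalisation 4. Noise of dim probes in the processed signal stays open: adding 50 to that signal gave 8 calls, fewer than the 0.5 of the normexp count set as the bound before the test, but that bound assumed that one constant acts alike on both signals, and adding 100 gave 34. Values distorted by normexp also stay open, because the test, in which 100% of the 58 kept direction without overlap in the processed signal, was run on probes chosen for that separation.

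The excess of small p-values was absent in 1 setting, normexp with median scaling, which gave 645 probes where 1066 would be expected, and it was not tested to a share under 0.05, which 10 splits do not allow. The labelled split gave 2612 probes at an unadjusted p under 0.05, the highest count of the 10 splits (1 of 10), and the highest other, with control replicate 3 and HaWRKY10 replicate 2 exchanged, gave 2479. That split puts both arrays of slide 2 on one side and both of slide 3 on the other, so its count can hold a slide difference; it also gave 34 calls after normexp. The 3 other splits that part every slide pair, as the labelled one does, gave 263 to 765 probes, and 0 calls after normexp; all 8 besides the labelled and the exchanged split gave 263 to 1032 probes. With slide as a block, the labelled split gave 3212. Probes detected on all arrays of one side and none of the other numbered 67 in the labelled split, 31 to 50 in these 3 splits and 31 to 61 over all 9 others.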
